A study of Mus musculus with 9 samples.

How the data were processed

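The source data were read counts per gene and library as deposited: the authors provided 1 table of unnormalized counts for 56748 genes in 9 libraries, with Ensembl identifiers, symbols, coordinates, biotypes and lengths. Per the labels, total RNA came from the brains of 7-month-old mice without the cerebellum, and libraries were sequenced on an Illumina platform. The processing notes name the genome build GRCm39. The aligner, the counting tool, the handling of reads that match several genes and the strandedness are not given in the sources used here. The values were checked to be whole numbers. Groups were taken from the genotype in the labels: wild-type, 5xFAD and 5xFAD/Cd5l tg/wt, with 3 libraries each and each library titled as a separate mouse. The libraries held 14575416 to 17865150 counts, and 3 counts over the 5xFAD group corresponded to 0.0627 CPM. The interval and floor given for Cd5l cover counting error only. The interval for Rgs6 comes from the SE of the fit, and that for TEC gene models from resampling the models.

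Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15, grouped by genotype), which left 17575 genes and removed at most 0.161% of a library's counts. Counts were scaled by TMM (factors 0.987 to 1.018), and all 9 libraries were fitted at once with 1 coefficient per genotype by edgeR's quasi-likelihood method (edgeR 4.0.16, limma 3.58.1, R 4.3.3). The 3 comparisons were 5xFAD against wild-type, 5xFAD/Cd5l tg/wt against 5xFAD, and 5xFAD/Cd5l tg/wt against wild-type. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic. CPM were computed with the scaled library sizes. The Fisher exact test compared the biotypes of passing genes with all tested genes.

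The test was tried on simulated counts with the means, depths and dispersions of these libraries, in which 200 genes were changed. For 5xFAD against wild-type, 41.8%, 67.2% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 8.16% of calls were false. For 5xFAD/Cd5l tg/wt against 5xFAD the shares were 44.8%, 67.2% and 89.4%, with 8.22% false calls. For 5xFAD/Cd5l tg/wt against wild-type they were 44.8%, 70.2% and 90.9%, with 6.16% false calls.

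37 gene lists with 701 members, of which 3 had no matching symbol, covered microglial states, phagocytosis, complement, interferon, antigen presentation, inflammation, astrocytes, neurons, oligodendrocytes, vessels, lipid and lysosomal metabolism, amyloid processing, stress responses, mitochondria, ribosomal proteins, blood, borders of the brain, brain regions and sex-linked genes. The 34 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, which tests whether a list moves one way on balance without comparing it with other genes. Members were counted over all tested genes and adjusted over the list alone. Several lists share members, such as Trem2 and Axl. For the overlap of comparisons that share libraries, 100 data sets without effects were simulated.

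The lists, tests, thresholds and alternatives were chosen before the data were examined, and so was the rule for named genes: Cd5l, App and Thy1, the 10 rising and 10 falling genes with the smallest p among those that passed, had a mean of at least 1 CPM and showed no overlap between the libraries of the compared genotypes, up to 4 members of each list with the smallest p, and up to 10 genes that passed in both crossed comparisons for each relation of signs. Malat1, Acsl3, Naip5, Cd33, Hpgds, Tcirg1, Slc18a2, Car8 and Gch1 were chosen after their values were seen. Other genes that the rule names, 1 of them for every comparison, are not reported here.

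Other choices tried were RLE, upper-quartile and total-count scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the 6 libraries compared, the replicate number as a block, removal of mitochondrial, globin and ribosomal RNA genes, other thresholds, and leaving out each library in turn. Chosen later were offsets that remove each library's trend on gene length or GC content, and a fit without wild-type library 3 and 5xFAD/Cd5l tg/wt libraries 2 and 3, whose regional marker genes stood apart. GC content came from transcripts of an older mouse annotation matched by Ensembl identifier, with a value for 17293 of 17575 tested genes (98.4%). Libraries with the same replicate number were not more alike than others, since their correlations after removal of genotype means ran from -0.100 to 0.154, so that the comparisons were not paired. The sex of the animals is not labelled. Because no library had more than 1 count at a Y-linked gene, a sex covariate would not vary and was left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.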

Results

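Transcript levels were measured by bulk RNA sequencing in brain tissue of 7-month-old mice, taken without the cerebellum per the labels. Each of 3 genotypes had 3 libraries, each labelled as 1 mouse: wild-type, 5xFAD, and 5xFAD/Cd5l tg/wt. 5xFAD mice carry mutant human transgenes, APP among them, driven by the neuronal Thy1 promoter, and accumulate amyloid. The third genotype adds a mouse Cd5l transgene under the human PDGF-B promoter. CD5L is a secreted scavenger-receptor protein made by tissue macrophages. The wild-type libraries held 16919592, 16460907 and 14575416 counts. The 5xFAD libraries held 15279393, 17865150 and 14932825 counts, and the 5xFAD/Cd5l tg/wt libraries held 14981564, 15040941 and 17650469 counts. After filtering, 17575 genes were tested. Values are given as log2 fold changes ± SE from a fit with n = 3 libraries per genotype, or CPM (counts per 1e6 counts of the scaled library, mean ± SD, n = 3). Adjusted p-values come from edgeR's quasi-likelihood test.

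The comparison of 5xFAD with wild-type mice asked what the amyloid model alone changed, and its largest rises among the genes named here were microglial. Cst7, an inhibitor of lysosomal cathepsins (chromosome 2, 150412335 to 150420864, GRCm39), rose from 0.207 ± 0.0251 to 29.9 ± 9.85 CPM, a log2 fold change of 7.11 ± 0.36 (adjusted p = 8.38e-07). Clec7a, a phagocytic receptor of activated microglia (chromosome 6, 129438554 to 129449742), rose by 5.09 ± 0.33, and the integrin gene Itgax by 5.47 ± 0.43. Tyrobp, the signalling partner of Trem2, rose by 2.08 ± 0.16, Trem2 itself by 2.02 ± 0.16, and the lysosomal protease gene Ctsd went from 192 ± 2.59 to 474 ± 53.1 CPM. In the list of disease-associated microglia, 18 of 30 tested genes rose, none fell and 12 did not pass the threshold, and 25 rose when adjusted over the list alone. As a set this list rose with adjusted p = 3.04e-82 in camera, and with adjusted p = 0.0272 with an estimated correlation.

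Homeostatic microglial genes also rose, with 12 of 19 past the threshold (14 adjusted over the list alone, camera adjusted p = 2.73e-30, and 0.0272 with an estimated correlation). They included Csf1r, the receptor microglia need for survival, at 0.84 ± 0.09, and Fcrls at 1.54 ± 0.14. Among phagocytosis and scavenger receptors, 11 of 30 rose (16 rose and 1 fell adjusted over the list alone, adjusted p = 1.93e-20, and 0.0272 with an estimated correlation), among them Itgb2 at 1.48 ± 0.13 and the Fc receptor genes Fcgr3 at 1.27 ± 0.09 and Fcgr2b at 1.89 ± 0.17. The Fcgr genes are close paralogs, and the deposited counts do not show how reads that match several of them were assigned. Of the lysosome and autophagy genes, 11 of 30 rose (14 rose and 1 fell adjusted over the list alone, adjusted p = 9.06e-26, and 0.0334 with an estimated correlation), including the cathepsin gene Ctss at 1.39 ± 0.11. Mpeg1, which encodes a pore-forming protein of macrophages, rose by 1.98 ± 0.10 (chromosome 19, 12438143 to 12442647).

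Of 18 complement genes, 6 rose (7 rose and 1 fell adjusted over the list alone, adjusted p = 1.43e-12, and 0.0438 with an estimated correlation), among them the subunits of C1q, with C1qa at 1.38 ± 0.12, C1qb at 1.38 ± 0.11 and C1qc at 1.48 ± 0.10. In the list of inflammatory cytokines and NF-kB, 3 of 19 rose, both over all genes and adjusted over the list alone (adjusted p = 4.23e-05, and 0.0334 with an estimated correlation): the chemokine gene Ccl3 at 4.80 ± 0.41, Tgfb1 at 0.76 ± 0.15 and Cxcl16 at 1.34 ± 0.28. Tgfb1 did not pass without 5xFAD library 2 (adjusted p = 0.0726) or 3 (0.0600) or wild-type library 2 (0.0518), and Cxcl16 did not pass without any of 5xFAD libraries 1 and 3 or wild-type libraries 2 and 3 (adjusted p = 0.0602 to 0.0831). Antigen presentation genes rose in 5 of 17 cases (10 adjusted over the list alone, adjusted p = 8.74e-11), with B2m, the light chain of MHC class I, at 0.82 ± 0.12 and the class II chain gene Cd74 at 1.67 ± 0.23, but this list gave adjusted p = 0.127 with an estimated correlation.

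Gfap, the intermediate filament of reactive astrocytes (chromosome 11, 102778162 to 102791738), went from 232 ± 35.7 to 687 ± 32.9 CPM, a rise of 1.57 ± 0.12, and the protease inhibitor gene Serpina3n rose by 1.51 ± 0.21. These were the 2 of 17 reactive-astrocyte genes that passed (3 adjusted over the list alone, adjusted p = 0.000193, but adjusted p = 0.127 with an estimated correlation). Gpr17, a receptor of maturing oligodendrocyte precursors, rose by 0.75 ± 0.11 as the 1 passing gene of 11 (1 adjusted over the list alone, adjusted p = 0.00677, but adjusted p = 0.345 with an estimated correlation). The interferon response rose in camera (adjusted p = 0.00134, but adjusted p = 0.7 with an estimated correlation) with 1 of 28 genes, Bst2 at 1.10 ± 0.26, past the threshold over all genes or adjusted over the list alone. Bst2 did not pass without wild-type library 2 or 3 or without any 1 of the 5xFAD libraries (adjusted p = 0.0502 to 0.146), and the list did not pass without wild-type library 2 (0.106) or 5xFAD library 3 (0.0872).

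**Figure D1:**
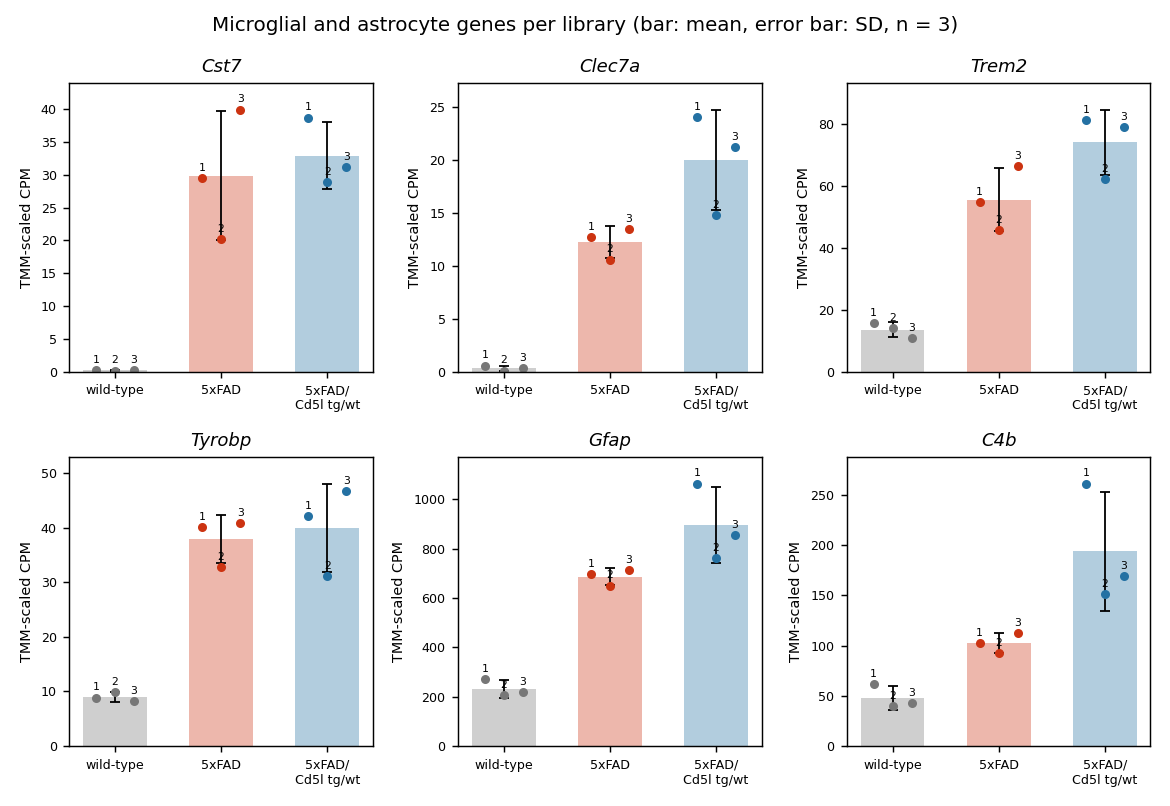
CPM of Cst7, Clec7a, Trem2, Tyrobp, Gfap and C4b in each library, with bars at the genotype mean and error bars of 1 SD (n = 3 libraries). All 6 genes were higher in both amyloid genotypes than in wild-type mice, and C4b was also called higher in 5xFAD/Cd5l tg/wt than in 5xFAD.

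More genes fell than rose in 5xFAD mice. Meg3, an imprinted long non-coding RNA (chromosome 12, 109506879 to 109538165), fell by 1.59 ± 0.16 on the log2 scale, from 1463 ± 264 to 485 ± 47.8 CPM (adjusted p = 0.000129). Clk1, a kinase that regulates splicing factors (chromosome 1, 58449348 to 58463225), fell by 1.10 ± 0.10. Rnpc3 and Snrnp70, which encode parts of the spliceosome, fell by 1.12 ± 0.11 and 0.69 ± 0.07, and Leng8 fell by 1.03 ± 0.11. Xist, the RNA that coats the inactive X chromosome, fell by 0.89 ± 0.09, and the nuclear RNA Firre by 0.92 ± 0.09. Xist overlaps Tsix on the opposite strand, and the strandedness of the libraries is not given. Malat1, a nuclear-speckle RNA named here after its values were seen, fell by 1.75 ± 0.19. Long non-coding RNAs made up 64 of the 428 falling genes and 11.4% of the tested genes (Fisher's exact test, two-sided, p = 0.0206), and 116 of the 939 genes that rose in 5xFAD/Cd5l tg/wt against 5xFAD (p = 0.315). The share of long non-coding RNAs in all counts was 1.17% ± 0.0261 in 5xFAD, against 1.46% ± 0.0980 in wild-type and 1.55% ± 0.139 in 5xFAD/Cd5l tg/wt libraries (SD, n = 3).

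Vessel genes fell as well. All 22 tested genes of endothelium and mural cells had negative log2 fold changes, and 6 passed (10 adjusted over the list alone, adjusted p = 2.84e-12, and 0.0334 with an estimated correlation). Slco1a4, an organic anion transporter of the blood-brain barrier, fell by 1.12 ± 0.15, the drug efflux pump gene Abcb1a by 0.85 ± 0.08, and the pericyte gene Rgs5 by 0.52 ± 0.07. Abcb1a has the close paralog Abcb1b, with which reads may be shared. Hindbrain and cerebellum genes fell as a list (1 of 17 past the threshold, Cbln3, and 9 adjusted over the list alone, adjusted p = 0.000903, but adjusted p = 0.63 with an estimated correlation). Wild-type library 3 carried 192 CPM of the granule-cell gene Cbln3, against 18.5 and 2.98 CPM in the other wild-type libraries. Without that library Cbln3 did not pass (adjusted p = 0.14) and neither did the list (adjusted p = 0.143). Cbln3 did not pass either without any 1 of the 5xFAD libraries (0.0914 to 0.192) or without 5xFAD/Cd5l tg/wt library 2 (0.0553) or 3 (0.0663), with limma-voom (0.459), in a fit of only the 6 libraries compared (0.0636) or without wild-type library 3 and 5xFAD/Cd5l tg/wt libraries 2 and 3 together (0.0666).

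Heat shock genes rose as a list without a single passing gene of 19 (0 adjusted over the list alone, adjusted p = 0.00102, but adjusted p = 0.623 with an estimated correlation). The same held for ribosomal proteins (0 of 36, 4 adjusted over the list alone, adjusted p = 7.7e-08, but adjusted p = 0.546 with an estimated correlation) and for ependyma (0 of 9, 0 adjusted over the list alone, adjusted p = 0.0108, but adjusted p = 0.353 with an estimated correlation, and 0.0776 without 5xFAD library 3). Among amyloid processing genes, Clu alone passed, of 20, at 0.31 ± 0.07 (1 adjusted over the list alone, list adjusted p = 0.555), and it did not pass without any 1 of the 6 libraries compared (adjusted p = 0.0511 to 0.133). App (1960 ± 13.8 CPM in 5xFAD, 2005 ± 110 in wild-type) did not pass, and the reference holds the mouse gene, not the human transgene. Thy1, whose promoter drives the transgenes, rose by 1.27 ± 0.08 (chromosome 9, 43954681 to 43959876, adjusted p = 4.27e-06). Counts at Thy1, here and in the other comparisons, do not separate the endogenous gene from any transgene transcripts that carry Thy1 sequence. Synaptic genes (0 of 31, adjusted p = 0.291), immediate early genes (0 of 21, 0.61), inhibitory interneurons (0 of 19, 0.849), myelin (0 of 20, 0.363), astrocyte identity (0 of 15, 0.13), cholesterol metabolism (0 of 30, 0.139), NRF2 (0 of 13, 0.215), oxidative phosphorylation (0 of 24, 0.586) and mitochondrially encoded genes (0 of 13, 0.682) did not move as lists, and none of these lists had a passing gene adjusted over the list alone. Neither did border-associated macrophages (0 of 7, 1 adjusted over the list alone, 0.468), meninges (0.599), choroid plexus (0.682), striatum (0.481), hippocampus (0.063), cortex (0.555), thalamus (0.527), hypothalamus (0.586) or olfactory bulb (0.858), each of the last 8 with 0 genes past the threshold over all genes or adjusted over the list alone. Without 5xFAD library 3, immediate early genes fell (adjusted p = 0.0114), and without wild-type library 3 astrocyte identity rose (adjusted p = 0.00685). The hippocampus list rose without wild-type library 2 (0.0267), 5xFAD library 3 (0.0447) or 5xFAD/Cd5l tg/wt library 1 (0.019) or 3 (0.0325), and in a fit of only the 6 libraries compared (0.0161), cholesterol metabolism and astrocyte identity without 5xFAD library 1 (0.0128 and 0.0392), and synapse and striatum without wild-type library 2 (0.0345 and 0.00791). Wild-type library 3 and 5xFAD/Cd5l tg/wt libraries 2 and 3 stood apart in regional marker genes. Without these 3 libraries, astrocyte identity (0.000478), cholesterol metabolism (0.0344), hippocampus (0.0211), thalamus (0.00021) and olfactory bulb (0.00207) rose, and the fall of hindbrain and cerebellum did not pass (0.112). Synapse rose with offsets for gene length (0.0256).

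In all, 615 genes passed in 5xFAD compared with wild-type mice, of which 187 rose and 428 fell, and 104 rose and 134 fell more than 2-fold. At an unadjusted p under 0.05 the count was 2861. Libraries of the genotypes did not overlap for 24.3% of tested genes, where chance gives 10% on average. Genes move together, so 1 shift common to many genes can move this share far from 10%. Its spread was not computed in any comparison. The count fell to 206 without 5xFAD library 1, 241 without 5xFAD library 2, 392 without 5xFAD library 3, 387 without wild-type library 1 and 291 without wild-type library 2.

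The comparison of 5xFAD/Cd5l tg/wt with 5xFAD mice asked what forced Cd5l expression changed in the amyloid model. Cd5l (chromosome 3, 87265188 to 87278380) had 2553, 2822 and 3551 counts in the 5xFAD/Cd5l tg/wt libraries, or 187 ± 15.5 CPM, and 0 counts in each 5xFAD library. It was at least 2982-fold higher, against a floor of 3 counts over the 5xFAD group (0.0627 CPM, counting error only). The wild-type libraries held 1 Cd5l count in total, so that no fold is given between 5xFAD and wild-type mice. 5xFAD/Cd5l tg/wt against wild-type gave a ratio of 8990 with a 95% exact Poisson counting interval of 1610 to 355000. Counts at Cd5l do not separate the transgene from the endogenous gene. Thy1 was 1834 ± 160 CPM in 5xFAD/Cd5l tg/wt and 1530 ± 79.0 CPM in 5xFAD, a difference of 0.26 ± 0.08 (adjusted p = 0.0604) that passed without 5xFAD/Cd5l tg/wt library 2 (adjusted p = 0.0386) or wild-type library 3 (0.0392). It also passed with DESeq2 (0.0446), without a filter (0.011), with offsets for gene length (0.045) and without the 3 libraries apart in regional markers (0.0281).

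Of the 939 rising genes, 360 were ones that had fallen in 5xFAD mice. Meg3 rose by 2.01 ± 0.16 to 1954 ± 431 CPM (adjusted p = 8.77e-05), Clk1 by 1.27 ± 0.10, Rnpc3 by 1.32 ± 0.11 and Leng8 by 1.33 ± 0.11. Ints6l, from a family of Integrator subunits, rose from 31.7 ± 1.03 to 78.0 ± 13.6 CPM, and Wsb1, which encodes a ubiquitin ligase adaptor, from 55.4 ± 4.79 to 114 ± 7.20 CPM. The phospholipid flippase gene Atp11b rose by 1.06 ± 0.09. Malat1 rose by 2.06 ± 0.20. Vessel genes were also higher than in 5xFAD. All 22 endothelial and mural genes had positive log2 fold changes and 9 passed (15 adjusted over the list alone). Camera gave adjusted p = 1.1e-11, but 0.15 with an estimated correlation. The same 5xFAD libraries enter the earlier fall and this rise, so they are not independent. With the transgene the list did not differ past the threshold from wild-type (median log2 fold change 0.0706, camera adjusted p = 0.394). A shift common to the 5xFAD libraries would give the same pattern, and this was not tested for the list. Slco1a4 rose by 1.23 ± 0.15, Abcb1a by 0.90 ± 0.08, Flt1, a VEGF receptor gene, by 0.72 ± 0.10 and Rgs5 by 0.66 ± 0.07. The 315 tested gene models of the biotype TEC had a median log2 fold change of -0.402 in 5xFAD against wild-type and 0.48 in this comparison. Nuclear ribosomal RNA genes took 0.2367% of counts in 5xFAD and 0.09611% in 5xFAD/Cd5l tg/wt libraries (mean, n = 3).

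Rgs6, which encodes a regulator of G-protein signalling (chromosome 12, 82635066 to 83208830), had the smallest p of the falling genes. It dropped by 1.00 ± 0.08 on the log2 scale, from 59.6 ± 4.66 CPM in 5xFAD to 29.7 ± 0.161 CPM (adjusted p = 8.77e-05), and wild-type mice had 59.7 ± 2.46 CPM. Scg2, a precursor of secretory-granule peptides, fell by 0.85 ± 0.13, Doc2b, which encodes a calcium sensor of vesicle release, by 0.62 ± 0.09, and Marcksl1 by 0.55 ± 0.08. The nicotinic receptor gene Chrna3 fell by 2.74 ± 0.41, from 3.44 ± 0.560 to 0.517 ± 0.417 CPM. It was at 0.9987 CPM in 5xFAD/Cd5l tg/wt library 1 and 0.2697 and 0.2821 CPM in libraries 2 and 3. It fell by 3.60 without library 1, and by 1.79 without the 3 libraries apart in regional markers (adjusted p = 0.033). Six3, a transcription factor gene listed for the striatum, fell by 0.67 ± 0.11, and it did not pass without the 3 libraries apart in regional markers (adjusted p = 0.0616).

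Microglial lists did not pass between the amyloid genotypes with TMM scaling of all 9 libraries and no offsets. Disease-associated microglia had 1 of 30 genes past the threshold (2 rose and 1 fell adjusted over the list alone, adjusted p = 0.114), the inhibitory receptor gene Lilrb4a at 1.94 ± 0.33, which did not pass without the 3 libraries apart in regional markers (adjusted p = 0.0923). The list rose without 5xFAD library 3 (adjusted p = 0.0208) or 5xFAD/Cd5l tg/wt library 2 (0.000512). Homeostatic microglia (0 of 19, adjusted p = 0.32, and 0.0483 without 5xFAD library 3), phagocytosis receptors (0 of 30, 0.32) and antigen presentation (0 of 17, 0.114, but 0.0099 without 5xFAD library 1 and 0.0108 without 5xFAD/Cd5l tg/wt library 2) had no gene past the threshold, over all genes or adjusted over the list alone. Complement had 1 of 18 (2 adjusted over the list alone, adjusted p = 0.214, and 0.0153 without 5xFAD/Cd5l tg/wt library 2), C4b at 0.92 ± 0.19, which did not pass without 5xFAD library 1 (adjusted p = 0.0814) or 2 (0.101). C4b has the close paralog C4a. Il1a rose by 1.41 ± 0.29 as 1 of 19 inflammatory genes (1 adjusted over the list alone, adjusted p = 0.07, and 0.0461 without 5xFAD library 3) and did not pass without 5xFAD library 1 (0.0814) or 2 (0.0965) or 5xFAD/Cd5l tg/wt library 3 (0.0569). Reactive astrocytes had 1 of 17 genes past the threshold (5 adjusted over the list alone, adjusted p = 0.113, and 0.0159 without 5xFAD/Cd5l tg/wt library 2). Lysosomal genes had 1 of 30 (1 adjusted over the list alone, 0.673).

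Without the 3 libraries apart in regional markers, where 5xFAD/Cd5l tg/wt is left with library 1, disease-associated microglia (adjusted p = 4.69e-06), phagocytosis receptors (0.0188), complement (0.0194) and reactive astrocytes (3.69e-05) rose against 5xFAD. With offsets for gene length, disease-associated microglia (0.0453), antigen presentation (0.0446) and inflammatory genes (0.0294) rose. Il1a did not pass without the 3 libraries (0.116).

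Interferon genes rose as a list (adjusted p = 0.000198, but adjusted p = 0.665 with an estimated correlation), with 3 of 28 past the threshold and 5 adjusted over the list alone. Stat2, a transcription factor of the interferon response, rose by 0.57 ± 0.11, and it did not pass without 5xFAD library 1 (adjusted p = 0.0505) or 2 (0.0692), or without the 3 libraries apart in regional markers (0.0832). Of the oxidative phosphorylation genes 22 of 24 had negative log2 fold changes and 2 passed (7 adjusted over the list alone, adjusted p = 6.83e-05, but adjusted p = 0.595 with an estimated correlation). With fry, inhibitory interneurons and oxidative phosphorylation fell and the inflammatory list rose (adjusted p = 0.0235 each), and endothelium and mural cells rose (0.00584). Other lists that fell in camera were heat shock, with 1 of 19 past the threshold (7 fell and 1 rose adjusted over the list alone, adjusted p = 0.000315, but adjusted p = 0.665 with an estimated correlation), inhibitory interneurons, with 1 of 19 (2 adjusted over the list alone, 0.00488, but adjusted p = 0.237 with an estimated correlation), myelin, with 0 of 20 (0 adjusted over the list alone, 0.000553, but adjusted p = 0.697 with an estimated correlation), and ribosomal proteins, with 0 of 36 (0 adjusted over the list alone, 0.000987, but adjusted p = 0.697 with an estimated correlation). Without 5xFAD/Cd5l tg/wt library 2, myelin gave adjusted p = 0.14 and ribosomal proteins 0.122, and without the 3 libraries apart in regional markers they gave 0.636 and 0.17. With offsets for gene length ribosomal proteins gave 0.0575.

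Some regional marker genes split the libraries of 1 genotype. The lists of thalamus (1 of 12, 1 adjusted over the list alone, adjusted p = 0.000205), hypothalamus (0 of 8, 0.00349), hindbrain and cerebellum (0 of 17, 0.000224), hippocampus (1 of 12, 3 adjusted over the list alone, 0.00281), striatum (2 of 16, 2 adjusted over the list alone, 0.013), olfactory bulb (0 of 9, 0.0319) and ependyma (1 of 9, 1 adjusted over the list alone, 0.0234) fell in camera, and none did with an estimated correlation (adjusted p = 0.48 to 0.697). The 3 of these lists with 0 passing genes also had 0 adjusted over the list alone. Pmch, a hypothalamic neuropeptide precursor, had 31.2 CPM in 5xFAD/Cd5l tg/wt library 1 but 0.135 and 0.169 CPM in libraries 2 and 3. Slc18a2, the vesicular monoamine transporter gene, had 18.04 CPM in library 1 but 0.337 and 0.959 CPM in libraries 2 and 3. Without libraries 2 and 3 of this genotype and wild-type library 3, the hypothalamus list rose instead (adjusted p = 0.0131), and hindbrain and cerebellum (0.192), ependyma (0.483) and olfactory bulb (0.115) did not pass. Ependyma did not pass with offsets for gene length (0.0578), nor olfactory bulb with offsets for GC content (0.0548). Leaving out single libraries ended the calls of striatum (0.692 without 5xFAD/Cd5l tg/wt library 1), ependyma (0.0879 without 5xFAD library 3, 0.106 without 5xFAD/Cd5l tg/wt library 3) and olfactory bulb (0.0633 and 0.26 without 5xFAD/Cd5l tg/wt library 2 or 3, and 0.0879 without 5xFAD library 3).

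**Figure D2:**
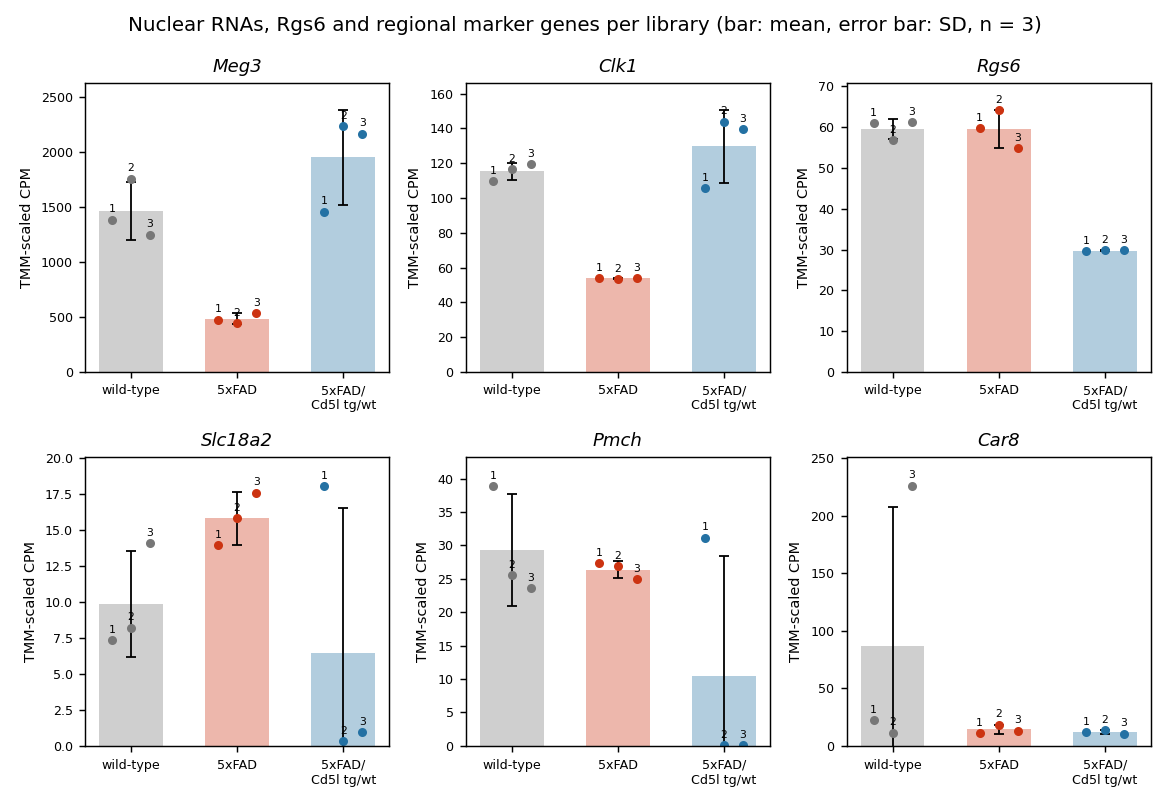
CPM of Meg3, Clk1, Rgs6, Slc18a2, Pmch and Car8 in each library, with the genotype mean and 1 SD (n = 3 libraries); lower error bars that would pass below 0 end at the axis. Slc18a2 and Pmch were near 0 in 5xFAD/Cd5l tg/wt libraries 2 and 3 alone, and Car8 was high in wild-type library 3 alone.

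The lists of astrocyte identity (2 of 15 fell, 2 adjusted over the list alone, adjusted p = 0.0548), synapse (1 of 31 rose, 1 adjusted over the list alone, 0.114), immediate early genes (1 of 21 fell, 1 adjusted over the list alone, 0.976), oligodendrocyte precursors (0 of 11, 0.237), cholesterol metabolism (1 of 30 rose, 1 adjusted over the list alone, 0.288), amyloid processing (0 of 20, 0.506), NRF2 (0 of 13, 0.0722), mitochondrially encoded genes (0 of 13, 0.3), border-associated macrophages (0 of 7, 0.47), meninges (0 of 13, 0.32), choroid plexus (0 of 16, 0.114) and cortex (2 of 14 rose, 5 rose and 2 fell adjusted over the list alone, 0.289) did not move, and those with 0 genes also had 0 adjusted over the list alone. Without 5xFAD/Cd5l tg/wt library 1, synapse (adjusted p = 0.0189) and immediate early genes (0.047) rose, while NRF2 (0.0277), meninges (0.0189) and astrocyte identity (0.0189) fell. Astrocyte identity also fell without 5xFAD library 1 (0.0177), 5xFAD/Cd5l tg/wt library 3 (0.04), or wild-type library 2 (0.0445) or 3 (0.0364), with RLE scaling (0.0487) or in a fit of only the 6 libraries compared (0.0458), choroid plexus without 5xFAD/Cd5l tg/wt library 3 (0.000466) or 5xFAD library 2 (0.0488), and cholesterol metabolism rose without 5xFAD library 3 (0.0208). Without the 3 libraries apart in regional markers, immediate early genes (6.46e-11) and choroid plexus (9.85e-07) fell and meninges rose (0.0188). With offsets for gene length, astrocyte identity fell (0.0274) and mitochondrially encoded genes rose (0.0359). App did not differ past the threshold (adjusted p = 0.820).

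Between 5xFAD/Cd5l tg/wt and 5xFAD mice 1095 genes passed, of which 939 rose and 156 fell, and 296 rose and 18 fell more than 2-fold. At an unadjusted p under 0.05 the count was 3914. The libraries did not overlap for 28.7% of tested genes, where chance gives 10% on average. The count was 343 (329 up and 14 down) without 5xFAD library 1 and 278 (265 and 13) without 5xFAD library 2. It was 493 (456 and 37) and 450 (399 and 51) without 5xFAD/Cd5l tg/wt library 2 or 3, and 2069 (1376 and 693) without library 1 of that genotype. It was 630 (391 and 239) without the 3 libraries apart in regional markers.

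Crossing the comparisons, 363 genes passed in both with opposite signs, 360 that fell in 5xFAD and rose with Cd5l and 3 the other way (Doc2b, Marcksl1 and Acsl3). Both comparisons share the 5xFAD libraries, which alone makes opposite signs more frequent. In 100 simulated data sets without effects the mean was 0.04 such genes and the highest count 1. Independent lists of these sizes would share 24.5. The simulation drew each gene independently and held no shift common to the 5xFAD libraries. It therefore cannot tell an effect of the genotypes from such a shift. Across genes, the correlation of the log2 fold changes was -0.51, against -0.50 from sharing libraries alone, and their covariance was lower than the simulated one by -0.0653. Genes are not independent replicates. Of the 428 genes that fell in 5xFAD, 419 (97.9%) moved back and 9 also passed against wild-type. Of the 187 rising genes, 55 (29.4%) moved back. Both sets were chosen on the same 5xFAD libraries, which favours a move back, and no value without effects was simulated for these shares. On a scale with wild-type at 0 and 5xFAD at 1, the falling genes had a median of -0.135 in 5xFAD/Cd5l tg/wt mice (quartiles -0.267 and 0.0569), which became 0.19 (quartiles 0.00133 and 0.443) without the 3 libraries apart in regional markers. The 187 rising genes had a median of 1.14 (quartiles 0.924 and 1.27), which became 0.939 (quartiles 0.41 and 1.23) without those libraries and 0.956 without a filter. For whole lists, the ratio of the median log2 fold changes was 1.10 for disease-associated microglia, 1.39 for homeostatic microglia, 1.04 for phagocytosis, 0.769 for lysosome, 1.69 for complement, 1.63 for antigen presentation, 2.43 for inflammatory genes, 2.41 for reactive astrocytes and 2.99 for interferon. It was 1.10 for oligodendrocyte precursors, 1.53 for hindbrain and cerebellum, 0.363 for ribosomal proteins, 0.121 for ependyma, -0.168 for endothelium and mural cells and -0.429 for heat shock. No spread was computed for these ratios. Those of inflammatory genes, reactive astrocytes and interferon divide by small 5xFAD medians (0.204, 0.19 and 0.307). Against 5xFAD, inflammatory genes (camera adjusted p = 0.07), reactive astrocytes (0.113) and complement (0.214) did not pass. Interferon passed (0.000198), but not with an estimated correlation (0.665). With genes called without 1 of the 5xFAD libraries and set against that library alone, the medians were -0.142, -0.105 and -0.186 for falling and 1.15, 1.39 and 1.03 for rising genes. Of the 187, 147 also passed against wild-type, 3 were called back and 9 rose further. The 9 were C4b, Lilrb4a, Ptprc, Nckap1l, Ptpn6, Rasal3, Apbb1ip, Man2b1 and Olfr111, and 1 gene fell in both, the choline transporter gene Slc5a7. Without 5xFAD library 2, Slc5a7 (adjusted p = 0.0869), Acsl3 (0.131) and all of the 9 but Lilrb4a (0.101 to 0.215) did not pass in 5xFAD/Cd5l tg/wt against 5xFAD. Without 5xFAD library 1, Lilrb4a, C4b, Ptprc, Rasal3, Apbb1ip, Man2b1 and Olfr111 (0.0512 to 0.0837), Slc5a7 (0.147) and Acsl3 (0.196) did not pass in 5xFAD against wild-type. The 10 genes with the same sign in both compare with 13.8 for independent lists. The count of genes with opposite signs was 112 without 5xFAD library 1, 107 without 5xFAD library 2, 235 without wild-type library 1 and 132 without wild-type library 2. The 5xFAD group has too few libraries to be split between the comparisons, so part or all of the excess may come from the shared libraries.

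**Figure D3:**
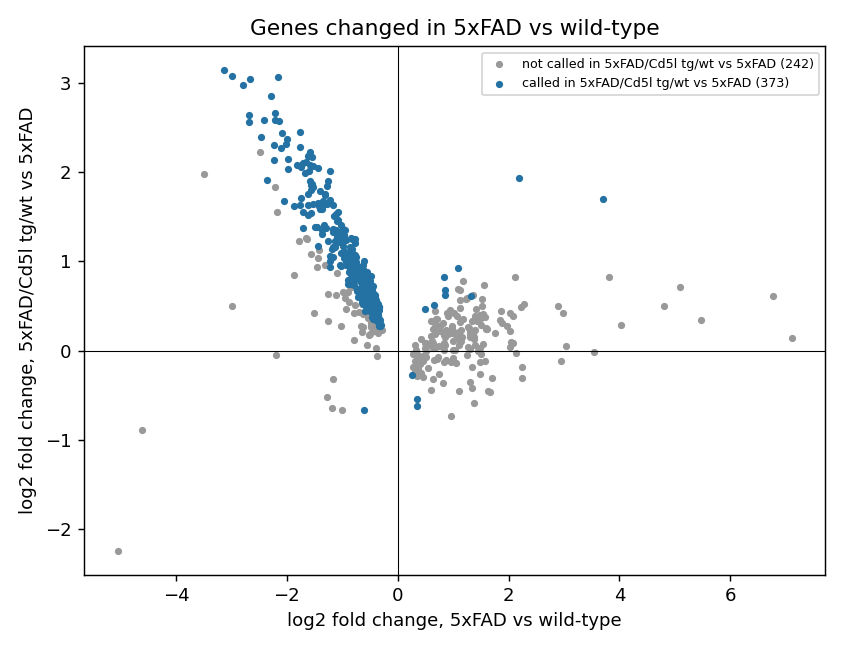
Log2 fold changes of the 615 genes changed in 5xFAD, with 5xFAD against wild-type on the horizontal axis and 5xFAD/Cd5l tg/wt against 5xFAD on the vertical axis. Colour marks the genes that also passed in the second comparison. Most falling genes lie in the upper left, and rising genes lie around 0 on the vertical axis.

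The comparison of 5xFAD/Cd5l tg/wt with wild-type mice asked which amyloid-linked changes were present with the transgene. Microglial genes rose again: Cst7 by 7.25 ± 0.36, Clec7a by 5.80 ± 0.32, Trem2 by 2.44 ± 0.16 (chromosome 17, 48653429 to 48661175, adjusted p = 5.44e-06), Itgb2 by 1.88 ± 0.13 and Mpeg1 by 2.26 ± 0.10. Of the disease-associated microglial genes, 21 of 30 rose (26 rose and 1 fell adjusted over the list alone, adjusted p = 3.11e-106, and 0.00859 with an estimated correlation). Homeostatic microglia (12 of 19, 14 rose and 1 fell adjusted over the list alone, 2.9e-40, and 0.00956 with an estimated correlation), phagocytosis receptors (14 of 30, 15 rose and 1 fell adjusted over the list alone, 8.92e-28, and 0.00956) and lysosomal genes (13 of 30, 14 adjusted over the list alone, 1.09e-30, and 0.0212) rose as well. Gfap rose by 1.95 ± 0.13 to 894 ± 154 CPM, and the oncostatin M receptor gene Osmr by 1.80 ± 0.23, as part of 5 of 17 reactive-astrocyte genes (7 rose and 1 fell adjusted over the list alone, 8.23e-10, and 0.0217 with an estimated correlation). Thy1 was higher by 1.53 ± 0.08.

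Complement genes rose in 8 of 18 cases (8 adjusted over the list alone, adjusted p = 6.59e-20, and 0.0212 with an estimated correlation), with C4b at 2.01 ± 0.20 and C1qb at 1.53 ± 0.11. Antigen presentation had 7 of 17 (15 adjusted over the list alone, 2.03e-19, and 0.0353 with an estimated correlation), with B2m at 1.13 ± 0.12 and the class I gene H2-D1 at 0.80 ± 0.13, whose reads may be shared with other H2 genes. Of the inflammatory list 4 of 19 rose (6 adjusted over the list alone, 8.06e-12, and 0.00859 with an estimated correlation), with Ccl3 at 5.30 ± 0.40 and Tgfb1 at 0.98 ± 0.15. All 28 interferon genes had positive log2 fold changes, with 3 past the threshold and 20 adjusted over the list alone (1.84e-17, but adjusted p = 0.13 with an estimated correlation).

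Among falling genes, Rgs6 dropped by 1.00 ± 0.08 (adjusted p = 1.37e-05). Slc5a7, the high-affinity choline transporter gene (chromosome 17, 54580618 to 54606062), dropped by 1.27 ± 0.14, from 19.8 ± 2.93 to 8.18 ± 1.10 CPM, with 12.9 ± 0.713 CPM in 5xFAD. The vesicular acetylcholine transporter gene Slc18a3 fell by 1.68 ± 0.26, the neurofilament gene Nefh by 0.96 ± 0.17 and the peripheral intermediate filament gene Prph by 1.82 ± 0.26. All 17 tested hindbrain and cerebellum genes had negative log2 fold changes in this comparison. Whether the falls of Slc5a7, Slc18a3, Nefh and Prph come from regional tissue content was not tested. Slc6a5, the glycine transporter gene of hindbrain neurons, fell by 4.20 ± 0.69 but had 32.8 ± 23.2 CPM in wild-type libraries, and without the 3 libraries apart in regional markers it did not pass (adjusted p = 0.0655), nor did it with limma-voom (0.115). Pcp4l1 (adjusted p = 0.0607) and Syt6 (0.0722) did not pass without those libraries either. Slc6a2, the noradrenaline transporter gene, was listed at 0.0666, 0 and 0 CPM in 5xFAD/Cd5l tg/wt libraries, against 2.16 ± 0.807 CPM in wild-type. It did not pass without 5xFAD/Cd5l tg/wt library 2 (0.0550) or 3 (0.0857), and the sensory peptide gene Calca did not without library 3 (0.0550). Neither Slc6a2 (0.179) nor Calca (0.162) passed without the 3 libraries.

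Inhibitory interneuron genes fell as a list (0 of 19, 3 adjusted over the list alone, adjusted p = 0.00102, and 0.0353 with an estimated correlation). Myelin (0 of 20, 7 fell adjusted over the list alone, 1.56e-08, but adjusted p = 0.343 with an estimated correlation), oxidative phosphorylation (0 of 24, 0 adjusted over the list alone, 7.15e-06, but adjusted p = 0.191 with an estimated correlation), thalamus (0 of 12, 0 adjusted over the list alone, 0.000122, but adjusted p = 0.4 with an estimated correlation), hypothalamus (0 of 8, 0 adjusted over the list alone, 0.0028, but adjusted p = 0.489 with an estimated correlation), olfactory bulb (0 of 9, 0 adjusted over the list alone, 0.0139, but adjusted p = 0.508 with an estimated correlation), striatum (0 of 16, 2 fell adjusted over the list alone, 0.0357, but adjusted p = 0.741 with an estimated correlation) and hindbrain and cerebellum (4 of 17, 13 adjusted over the list alone, 1.27e-14, but adjusted p = 0.141 with an estimated correlation) fell in camera. Without the 3 libraries apart in regional markers, the hypothalamus and olfactory bulb lists pointed up, while hindbrain and cerebellum still pointed down. Thalamus and myelin did not pass in that fit. It leaves 5xFAD/Cd5l tg/wt library 1 alone in its group, so differences in regional content may remain in it. Hypothalamus did not pass without 5xFAD/Cd5l tg/wt library 2 (0.055) or 3 (0.0612), olfactory bulb without wild-type library 3 (0.311) or 5xFAD/Cd5l tg/wt library 3 (0.205), and striatum without wild-type library 1 (0.0757) or 2 (0.735) or 5xFAD/Cd5l tg/wt library 1 (0.914).

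Synapse (0 of 31, 1 rose and 1 fell adjusted over the list alone, adjusted p = 0.000915, but adjusted p = 0.489 with an estimated correlation), cholesterol metabolism (1 of 30, 4 rose and 1 fell adjusted over the list alone, 0.00167, but adjusted p = 0.409 with an estimated correlation) and cortex (1 of 14, 2 adjusted over the list alone, 0.0357, but adjusted p = 0.464 with an estimated correlation) rose in camera. Synapse did not pass without 5xFAD/Cd5l tg/wt library 2 (0.105), nor cortex without wild-type library 3 (0.229), 5xFAD library 2 (0.0501) or 5xFAD/Cd5l tg/wt library 2 (0.208) or 3 (0.0799). Synapse (0.42) and cortex (0.212) did not pass and pointed down without the 3 libraries apart in regional markers. Cortex did not pass with offsets for gene length (0.0747) or in a fit of only the 6 libraries compared (0.0576). Endothelial and mural genes did not move (0 of 22, 0 adjusted over the list alone, adjusted p = 0.394). Nor did astrocyte identity (0.543), immediate early genes (0.585), oligodendrocyte precursors (0.185), amyloid processing (0.992), heat shock (0.394), NRF2 (0.479), mitochondrially encoded genes (0.463), ribosomal proteins (0.178), border-associated macrophages (0.899), meninges (0.585), choroid plexus (0.144), ependyma (0.899) or hippocampus (0.132). Of these 13, amyloid processing and heat shock had 1 passing gene each, Clu and Atf3, and the others 0; adjusted over the list alone, amyloid processing had 2 up and 1 down, heat shock and oligodendrocyte precursors 1 up, and the others 0. Immediate early genes turned with the library left out, up without 5xFAD/Cd5l tg/wt library 1 (0.0134) and down without library 2 (0.0445). Without single libraries, meninges (0.0134, 5xFAD/Cd5l tg/wt library 1), choroid plexus (0.000248, 5xFAD/Cd5l tg/wt library 3, and 0.00452, wild-type library 3), hippocampus (0.039, 5xFAD/Cd5l tg/wt library 2, and 0.0169, wild-type library 1) and heat shock (0.0486, wild-type library 1) fell, and ribosomal proteins (0.000111, 5xFAD/Cd5l tg/wt library 2, and 0.0223, wild-type library 2) and mitochondrially encoded genes (0.024, wild-type library 3) rose. Without the 3 libraries apart in regional markers, immediate early genes (3.51e-17) and choroid plexus (1.25e-09) fell. Astrocyte identity (0.00896), oligodendrocyte precursors (0.0086), ribosomal proteins (0.0266), border-associated macrophages (0.0337) and meninges (0.0085) rose. Atf3 did not pass without any 1 of the wild-type or 5xFAD libraries or 5xFAD/Cd5l tg/wt library 3 (0.0501 to 0.189), with limma-voom (0.0766), in a fit of only the 6 libraries compared (0.0968) or without the 3 libraries (0.113). Clu did not pass in a fit of only the 6 libraries (0.112), nor without 5xFAD library 1 (0.0521) or 5xFAD/Cd5l tg/wt library 3 (0.103).

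Against wild-type, 277 genes passed in 5xFAD/Cd5l tg/wt mice, of which 242 rose and 35 fell, and 171 rose and 18 fell more than 2-fold. At an unadjusted p under 0.05 the count was 2177. The libraries did not overlap for 14.5% of tested genes, where chance gives 10% on average. The count was 686 (368 up and 318 down) without 5xFAD/Cd5l tg/wt library 1 and 158 (146 and 12) without library 3. It was 1062 (522 and 540) without a filter, 452 (318 and 134) with DESeq2 and 360 (252 and 108) without the 3 libraries apart in regional markers. With 5xFAD against wild-type it shared 156 genes of the same sign, 147 up and 9 down, against 3.43 for independent lists and a mean of 0.07 in simulated data without effects. The wild-type libraries are shared by both, and the simulation held no shift common to them. The lists of lymphocytes and granulocytes (1 tested gene), erythroid cells (2) and sex-linked genes (2) were too small to test as sets. Of their genes only Xist passed over all genes, in both comparisons that include 5xFAD; adjusted over the list alone, both erythroid genes rose and both sex-linked genes fell in 5xFAD against wild-type, and 1 sex-linked gene rose in 5xFAD/Cd5l tg/wt against 5xFAD. No library had more than 1 count at any of 4 Y-linked genes.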

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

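The offsets for gene length and GC content and the fit without the 3 libraries apart in regional markers were chosen only after the results were seen. That fit leaves 1 library of 5xFAD/Cd5l tg/wt, which is assumed to vary like the others. For 5xFAD against wild-type (615 genes), the count was 1354 without a filter, 238 with an absolute log2 fold change above 1, 958 at adjusted p under 0.1, 1154 without the 3 libraries (573 of them shared with the 615) and 206 to 850 with 1 library left out. For 5xFAD/Cd5l tg/wt against 5xFAD (1095), it was 2063, 314, 1940, 630 (331 shared) and 278 to 2069. For 5xFAD/Cd5l tg/wt against wild-type (277), it was 1062 without a filter, 452 with DESeq2, 176 with only the 6 libraries compared, 417 at adjusted p under 0.1 and 158 to 686 with 1 library left out. Without the 3 libraries it was 360 (163 shared). Thresholds and filters change these counts by construction. For the other settings the cause was not tested. The lists moved (15, 14 and 20) became 7, 0 and 9 with an estimated correlation and 9, 4 and 11 with fry, and 15 to 17, 14 to 18 and 18 to 21 with 1 library left out. The 363 genes with opposite signs became 717 without a filter, 596 at adjusted p under 0.1, and 107 to 538 with 1 library left out. The position of falling genes moved from -0.135 to 0.19 without the 3 libraries and ran from -0.229 to -0.0598 with 1 library left out. That of rising genes ran from 1.03 to 1.19 with 1 library left out, and was 0.939 without the 3 libraries and 0.956 without a filter. Of 65, 64 and 66 called genes followed singly in the 3 comparisons, 45, 25 and 46 kept their call without each library in turn, and 63, 42 and 44 without the 3 libraries. Of these, 0 changed direction. With the replicate number as a block, a pairing the values do not show, the counts were 506, 836 and 240, the astrocyte identity list fell in 5xFAD/Cd5l tg/wt against 5xFAD (0.0473), the cortex list did not pass against wild-type (0.0541), and Cbln3 (0.123) and Clu (0.061) did not pass in 5xFAD against wild-type. Differences near 0 changed sign, all with an adjusted p over 0.05. App in 5xFAD against wild-type ran from -0.0602 without wild-type library 3 to 0.0160 without wild-type library 1, and was 0.0365 with length offsets. App was -0.0697 in 5xFAD/Cd5l tg/wt against 5xFAD with length offsets. Against wild-type it ran from -0.0349 without wild-type library 3 to 0.0406 without wild-type library 1, and was 0.0228 without 5xFAD/Cd5l tg/wt library 3. The fitted log2 fold change of Cd5l stayed past the threshold throughout. The sex covariate was not run, since it would not vary.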

Other observations

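The tests of Rgs6, of regional tissue as a source of the genes that fell in 5xFAD mice and rose with the transgene, and of other splits of the libraries were chosen only after the results were seen. Genes called in the same direction against both other genotypes, and not between those, numbered 20 higher and 11 lower in 5xFAD/Cd5l tg/wt mice. Both calls use the same 5xFAD/Cd5l tg/wt libraries, which favours calls of the same sign. No value without effects was simulated for these counts. Of the 20, 4 genes are given that were chosen after their values were seen. Naip5, an inflammasome sensor with close Naip paralogs, was higher by 1.90 against 5xFAD and 1.94 against wild-type, and Hpgds, the prostaglandin D synthase of microglia and mast cells, by 0.84 and 1.36. Cd33, a sialic acid receptor linked to amyloid uptake, was higher by 0.58 and 0.81, and Tcirg1, a subunit of the lysosomal proton pump, by 0.60 and 0.64. Without 5xFAD library 2, all 4 lost their call against 5xFAD, with adjusted p = 0.0627 for Naip5, 0.15 for Hpgds, 0.13 for Cd33 and 0.0514 for Tcirg1. Against wild-type, Naip5 did not pass without 5xFAD/Cd5l tg/wt library 2 (0.055) or 3 (0.0669), nor Tcirg1 without library 3 (0.058), and neither Naip5 (0.227) nor Cd33 (0.0722) passed without the 3 libraries apart in regional markers.

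The 428 genes that fell in 5xFAD mice, most of which rose again with the Cd5l transgene, had a median log2 fold change of -0.767 in 5xFAD and 0.822 in 5xFAD/Cd5l tg/wt against 5xFAD. After offsets for gene length the median in 5xFAD was -0.722, with 353 genes still called lower, and after offsets for GC content -0.748, with 402 called lower. The trends spanned at most 0.568 log2 units in a library for length and 0.614 for GC content, and removing them left most of the fall. The genes were chosen in the same libraries without offsets, which favours such an outcome, so a bias of this kind is not excluded. Without the 3 libraries apart in regional markers the median in 5xFAD was again -0.767. Of these, only wild-type library 3 enters that comparison, so the size of the fall did not depend on this library. The genes were chosen with the libraries that remain, so the value cannot tell whether regional content made the fall. The rise then rests on 5xFAD/Cd5l tg/wt library 1 and stays open (0.578 as the lowest of 3 medians, each against a 5xFAD library not used to choose the genes). A smaller share of nuclear and unspliced RNA in the 5xFAD libraries remains a candidate explanation. Gene models of the biotype TEC, single-exon models from unspliced clones, had a median of -0.402 in 5xFAD over 315 models. The 95% bootstrap interval of -0.513 to -0.290 resampled gene models and does not measure the spread between mice. Of these models, 37 were called lower and so belong to the 428 falling genes. Each 5xFAD library gave TEC models a smaller share of counts (0.0812% to 0.0817%) than each other library (0.0955% to 0.121%). Nuclear ribosomal RNA genes took a larger share in each 5xFAD library (0.1845% to 0.2647%) than in each 5xFAD/Cd5l tg/wt library (0.06613% to 0.1214%), with 0.2555% in wild-type library 3 and 0.08163% and 0.05841% in the other 2, and whether such differences come from RNA preparation or from the genotype stays open, since the labels give no batch.

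Rgs6 stood at 0.499 of its 5xFAD level in 5xFAD/Cd5l tg/wt mice (95% interval 0.443 to 0.562). The 25 tested genes within 1 Mb had a median log2 fold change of 0.0662 against wild-type (lowest -1.02, highest 0.622) and 0 were called. This argues against a change of the whole region, but not against a change of part of it. Libraries 2 and 3 of this genotype differed from library 1 by at most 0.0150 log2 units, with a gap of 0.875 to the lowest other library. These values argue against the regional content that sets libraries 2 and 3 apart from library 1 as the source of the fall in Rgs6. A tissue difference common to the 3 libraries would give the same values and was not tested. A level near 0.5 may reflect loss of 1 allele, as an insertion of the transgene in Rgs6 would give, but regulation of both alleles cannot be told apart from it in gene counts.

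Regional genes split libraries within genotypes. Further cerebellar markers, listed before they were examined, were higher in wild-type library 3 than in libraries 1 and 2 by a median of 2.10 (4 of 4 tested; Car8 at 226 against 22.6 and 11.6 CPM). Further midbrain markers were lower in 5xFAD/Cd5l tg/wt libraries 2 and 3 than in library 1 by a median of -1.85. Of 10 listed, 7 were tested, and Gch1 among them did not differ (-0.00452). Hypothalamic markers were lower by -2.57 (9 of 9 tested, of 16 listed). Among these, Pmch (-6.82) and Hcrt (-5.87) belonged to the hypothalamus list tested earlier and add no new evidence. The other hypothalamic markers ran from -3.59 to -0.677. These values are consistent with cerebellar tissue left in 1 library and with ventral midbrain and hypothalamus missing from another 2. No biological explanation was tested, since these libraries share a genotype with the others.

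Each comparison of 6 libraries allows 10 splits into 3 and 3, too few for a share under 0.05. For 5xFAD against wild-type, 1 split, the real one, gave as many as 615 genes, and the highest other gave 3. For 5xFAD/Cd5l tg/wt against 5xFAD it was 1 split at 1095 genes, with 2 as the highest other, and against wild-type 1 split at 277 genes, with 1 as the highest other. For the lists moved, 6 splits gave at least the real 15 in 5xFAD against wild-type (highest other 17), 6 gave at least 14 in 5xFAD/Cd5l tg/wt against 5xFAD (highest other 19), and 2 gave at least 20 against wild-type (highest other 23). In each comparison, splits that mix the genotypes thus moved as many lists in camera as the real split. The counts of lists moved therefore do not set the genotypes apart.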
